A study of Homo sapiens with 21 samples.

How the data were processed

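Total RNA of H1 human embryonic stem cells and of their derivatives was sequenced on days 0, 1, 2, 4, 6, 8 and 14 of differentiation towards cardiomyocytes, with 3 libraries per day. RNA was extracted with Trizol and libraries were made with the standard Illumina procedure, per the labels. Per the submitters' processing notes, reads were aligned to hg38 with STAR 2.5.0, and Cufflinks 2.2.1 is also named there. The counting program, the strand setting and the annotation release are not given in the sources used here.

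The deposited values are raw counts per feature that the authors made from the aligned reads, without normalization. The table has 61564 rows, 60554 for annotated genes and 1010 for regions named yylnc (939 distinct names, 465 regions with an end minus start of 1000). The counts behave as if reads were counted over whole gene spans, introns included, regardless of strand, and in every feature they overlap, which is inferred from nested features. In 99.6% of 6536 nested pairs on the same strand and 99.2% of 8627 on opposite strands the outer feature held at least the counts of the inner one in every library, and the rest break the rule. Of all features, 36459 overlap another and 25105 do not, and 1491 were at 0 in every library. Where the counts of an overlapping feature reached 0.5 of the own counts of a gene given with a value, most such genes carry the name of that feature or a remark on shared reads. TTN, THBS2, RP11-815M8.1, FOXD3-AS1 and HAND2-AS1, and further mentions of HAND2, TBX2, ESRG, SOX2, POU5F1 and NPPA, carry neither but share reads to this extent. Genes named only for moving against their list or not passing carry none either. Of those that passed, TUBB3, PDGFRA, TNNI3, RNF43, PFKM, NR2F1, NR2F2, MYLK, KCNMB1, LIX1, LEFTY1, TP53INP1, THY1, PAX6, CA9 and LINC00881 share reads to this extent, so their own direction is uncertain. The column totals, from 78183339 to 117420971, are sums over features and only bound the number of reads, and 33471 to 35425 features per library held at least 10 counts. The day 14 totals were the highest 3. RNA of the 7SL family and the features overlapping it took 9.54% to 17.35% of counts and the mitochondrial ribosomal RNA MT-RNR2 5.4% to 14.17%. RPS29, PTPRD and ANKRD28 hold 7SL reads and were not interpreted. Gene types and neighbours came from a GENCODE table matched by name, place and strand for 34717 gene features, of which 68.5% had the same start and 96.9% starts within 100 kb.

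Gene lists, comparisons, tests and alternatives were fixed before the data were examined. Alternatives added later are marked as such. Features were kept by filterByExpr of edgeR 4.0.16 with day as the group (minimum count 10, minimum total 15), which left 40268. Counts were scaled by TMM and fitted in edgeR by robust quasi-likelihood to all 21 libraries with day as the factor. Each day was tested against the day sampled before it and day 14 against day 0, and an F test took all days together, with Benjamini-Hochberg adjustment over all tested features and a threshold of 0.05. For each list the adjustment was also made over its members alone. Genes whose lower day held at most 3 counts over its libraries are given as a ratio with a 95% counting interval, or as a lower bound when that day held 0.

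The 37 gene lists have 652 entries, of which 645 matched a feature and 630 were tested. They were tested in each of the 7 comparisons with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 259 tests, and again with the correlation estimated from the data. Where the report gives a single camera value for a list that passed, the call also held with an estimated correlation. The preset value treats list members as nearly independent, so the smallest camera p-values overstate the evidence. The lists were put together from general knowledge of these genes.

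Genes are named by a fixed rule. In each step of consecutive days these are the 6 largest rises and 6 largest falls among genes that passed with at least 10 CPM in the higher day and no overlap between the libraries of both days. From each list described these are up to 4 members with the largest fitted change among those that passed, or up to 2 where none passed. Further named genes are the 3 with the largest excess on each day of highest expression, the features within 100 kb of T, and the DNA methyltransferase genes. Members named only because they moved against their list or did not pass were chosen after their values were seen. Some genes picked by this rule are counted in the totals but not reported here. Folds come from the fitted log2 fold change. The day of highest expression was taken for features that changed and whose day means spanned at least 1 on the log2 scale, with a prior count of 2.

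Pairs join each lncRNA gene to the coding gene with the nearest start within 5 kb on the opposite strand, and each yylnc region to the gene in its name. The median Pearson correlation of log2 day means was compared with 10000 permutations of the partners. Alternatives were DESeq2 size factors, upper quartile factors, no filter and a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0 and limma voom as tests, the replicate number as a block, each library left out in turn, mitochondrially encoded genes left out, only the libraries of the days compared, and a threshold of at least 2-fold. Libraries were also regrouped across days. GC content and length were tested as a source of fold changes and explained 0.2% to 2.5% of their variance per comparison.

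The procedure was tested on simulated data drawn with the dispersion of the real libraries and, for day 8, the day 6 means, in which 200 of 39645 tested features were changed. Of features changed 1.5-fold, 2-fold and 4-fold, 34 of 67 (50.7%), 40 of 67 (59.7%) and 61 of 66 (92.4%) were recovered, with median folds of 1.51, 2 and 4.03. Of 138 features called, 3 (2.17%) had not been changed. A changed set of 20 genes gave a camera adjusted p of 1e-102 and 0 of 36 unchanged sets were called. The pair test was run on random normal values, not on simulated counts. For 500 such pairs the median correlation was 0.74 (permutation p = 0.001), the value they were made with, and 3 of 100 sets of unrelated pairs fell under 0.05. Computations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.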

Results

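Total RNA from H1 human embryonic stem cells, an established pluripotent line, was sequenced along their differentiation to cardiomyocytes. The 21 libraries fall into 7 sampling days with 3 replicates each. Day 0 holds the undifferentiated cells. By the labels, early mesoderm was sampled at day 1 and late mesoderm at day 2, mesoderm of cardiac type at day 4, progenitors of the heart at day 6, and cardiomyocytes at day 8 (early) and day 14. The deposited table holds raw counts for 61564 features, 60554 annotated genes and 1010 regions with names beginning yylnc. Its column totals are sums over features, not reads, as the counts behave as if a read is counted in every feature it overlaps. The labels do not say whether replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. Levels are CPM, counts relative to the scaled library total, as mean ± SD with n = 3 libraries per day, and log2 fold changes carry the standard error of the fit. Counting intervals and floors cover counting error only. The 3 day 14 libraries carry another run prefix than the other 18 libraries, so run and day 14 cannot be told apart in any comparison that uses that day. Mitochondrial transcripts took 14.88% to 17.16% of the counts at day 14 and 6.41% to 12.08% on the other days.

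The expression of most features moved over the course, from pluripotency genes at day 0 through streak and mesoderm genes at days 1 and 2 to genes of the contractile apparatus from day 4. In edgeR, 36724 of 40268 tested features (91.2%) changed across the 7 days, and 35690 of 39778 (89.7%) changed when days 0 to 8 were fitted without day 14. On the 1000 features of highest variance, the first principal component held 75.6% of the variance and the second 10.8%. Of 29725 features that changed and spanned at least a log2 range of 1, 24.7% had their highest level at day 0, 11.2% at day 1, 9.5% at day 2, 12.7% at day 4, 9.1% at day 6, 10.4% at day 8 and 22.3% at day 14. The genes with the largest excess on their own day were PRDM14, SOX2 and FOXD3-AS1 at day 0, NKX1-2, RP11-568A7.4 and RP11-415G4.1 at day 1, and MSGN1, WNT8A and T at day 2. They were the pepsinogen genes PGA3 and PGA4 with the overlapping CTD-2331C18.5 at day 4, WNT2, its overlapping transcript AC002465.2 and RP11-807H17.1 at day 6, MYH6, SERPINA1 and MIR208A, which lies inside MYH6, at day 8, and MYH7, CTD-2201G16.1, which lies inside MYH7, and MYL2 at day 14. Among long noncoding RNA (lncRNA) genes, 16.4% of 7514 peaked at day 0, 16.2% at day 4 and 22.3% at day 14, against 27.4%, 11.5% and 22.7% of 12666 protein-coding genes.

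**Figure D1:**
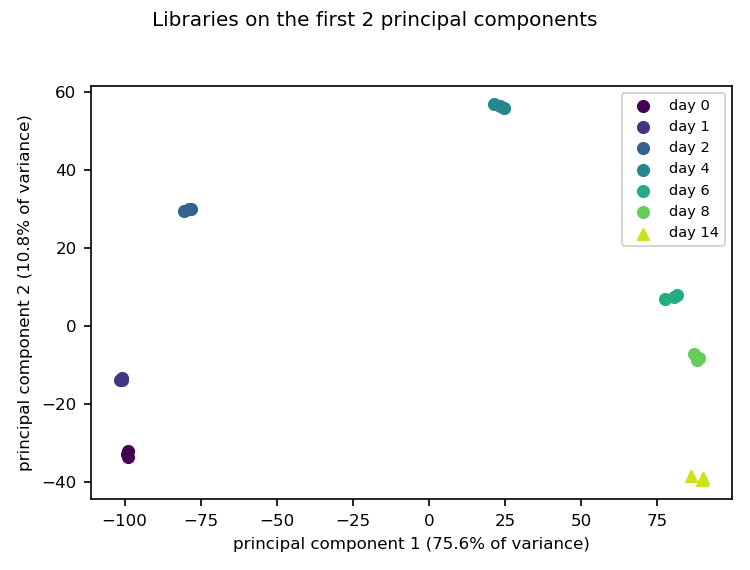
Scores of the 21 libraries on the first principal component (x axis, 75.6% of variance, no unit) and the second (y axis, 10.8%), from log2 CPM of the 1000 most variable features. Each point is a library coloured by day, and the 3 libraries of a day lie together.

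**Figure D2:**
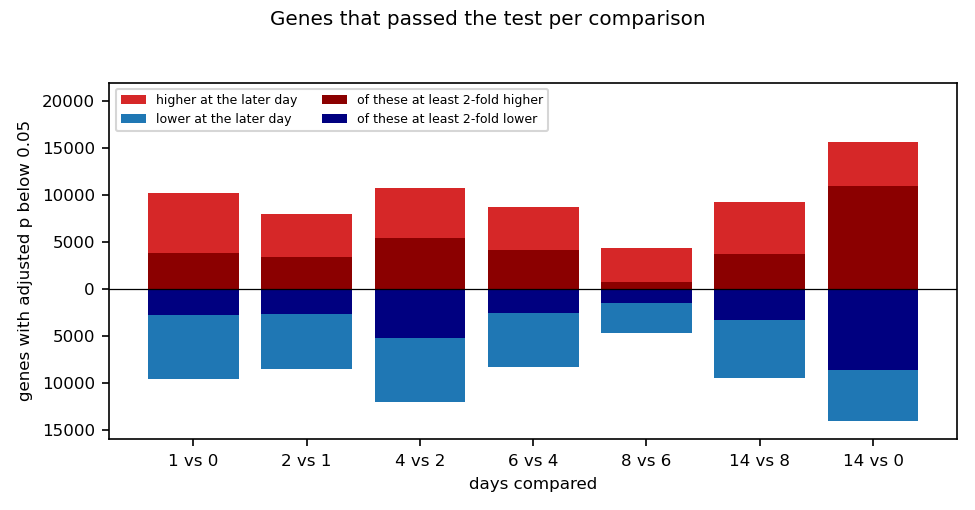
Number of features (y axis) that were higher or lower in each step between sampling days (x axis) at an edgeR adjusted p under 0.05, among 40268 tested. The most features changed between days 2 and 4 (22839) and the fewest between days 6 and 8 (9018) among steps of consecutive days.

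In the first day, from stem cells to early mesoderm, genes of the primitive streak, the transient embryonic structure from which mesoderm arises, switched on while part of the pluripotency and neural programme fell. TBXT (T in the deposited table), the Brachyury transcription factor of the streak, rose from 0.363 ± 0.075 to 99.1 ± 4.6 CPM, a log2 fold change of 8.09 ± 0.15. CDX2, a caudal homeobox factor of posterior mesoderm, rose 240-fold to 12.7 ± 1.5 CPM, and SP5, a target of WNT signalling, rose from 0.323 ± 0.069 to 31.2 ± 2.4. EVX1, a homeobox gene of the posterior streak, rose 426-fold to 26.0 ± 1.6 CPM. Its neighbours EVX1-AS (393-fold) and RP1-170O19.17, which is identical to yylncEVX1 (697-fold, to 14.8 ± 0.52 CPM), rose with it, but EVX1 and EVX1-AS share most of their span and their counts cannot be separated. Of 22 streak and early mesoderm genes, 18 rose, DLL3 and CER1 fell, and MSGN1 and FGF17 did not pass, with 21 passing when adjusted over the list alone (camera adjusted p = 4.9e-52). Of 15 feedback targets of the WNT pathway, 13 rose, FZD7 fell and NKD2 did not pass (14 adjusted over the list alone, camera adjusted p = 9.7e-35). Among them LEF1, a transcription factor partner of beta-catenin, rose from 1.28 ± 0.16 to 80 ± 5.1 CPM and CDX1 rose 83.5-fold. Of 12 BMP pathway targets, 10 rose and ID1 and SMAD7 did not pass, with 10 also passing adjusted over the list alone (camera adjusted p = 4.5e-11). MSX1 and MSX2, homeobox genes induced by BMP, rose 58.0-fold and 49.9-fold. The BMP antagonist NOG and the factor ATOH8 rose 10.7-fold and 8.6-fold.

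Of 20 pluripotency genes, 17 fell, FGF4 and GDF3 rose and TERT did not pass in the same step (19 adjusted over the list alone, camera adjusted p = 5.9e-16). SOX2 fell from 114 ± 3.5 to 5 ± 0.64 CPM, although its span lies inside the lncRNA SOX2-OT, whose reads it shares. PRDM14, a repressor of differentiation, fell 10.9-fold from 78.5 ± 3.5 CPM, and USP44, a deubiquitinase, fell 5.73-fold, while the growth factor FGF4 rose from 0.358 ± 0.15 to 6.10 ± 1.2 CPM. The largest falls also took in FOXD3, a stem cell and neural crest factor (from 10 ± 0.87 to 0.145 ± 0.011 CPM), its overlapping FOXD3-AS1, the cytoskeletal adaptor SORBS2 (28.9-fold), NPTX1, a pentraxin of neurons (26.4-fold), and SHISA2, a regulator of WNT and FGF receptors (23.3-fold). Of 15 neural genes, 10 fell, TUBB3 and LHX2 rose and 3 did not pass (12 adjusted over the list alone, camera adjusted p = 4.3e-06). OTX2, a forebrain factor, fell from 21.3 ± 0.76 to 2.41 ± 0.49 CPM and SOX3 fell 3.86-fold. Of 18 cardiac mesoderm genes, 11 rose, PDGFRA fell and 6 did not pass (12 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.056 with an estimated correlation). The apelin receptor gene APLNR rose 22.4-fold to 4.47 ± 0.13 CPM. MESP1 rose from 3 counts to 66 over the 3 libraries of a day, a ratio of 20.6 (95% counting interval 6.76 to 103), with a log2 fold change of 4.21, or 5.05 without day 0 replicate 2. FOXF1 rose from 1 count to 34, a ratio of 31.9 (5.35 to 1296), although under limma voom its adjusted p was 0.058 and its log2 fold change of 4.58 was 6.51 without day 0 replicate 1.

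Of 14 genes of epithelial to mesenchymal transition, 6 rose, CLDN6 and VIM fell and 6 did not pass at day 1 (8 adjusted over the list alone, camera adjusted p = 0.013). The repressor ZEB2 rose 11.7-fold and N-cadherin (CDH2) rose 2.3-fold to 146 ± 4.2 CPM, while the epithelial genes EPCAM (115 ± 4.1 and 114 ± 7.2 CPM) and ESRP1 (133 ± 2.2 and 137 ± 2) did not pass. All 27 tested cytosolic ribosomal protein genes fell (27 adjusted over the list alone, camera adjusted p = 2.3e-13, adjusted p = 0.25 with an estimated correlation). Of 19 cholesterol synthesis genes, 18 rose and FDFT1 did not pass (18 adjusted over the list alone, camera adjusted p = 3.8e-10, adjusted p = 0.093 with an estimated correlation). The reductase gene DHCR7 rose 2.38-fold. Of 16 p53 targets, 13 fell, SESN2 rose and ZMAT3 and XPC did not pass (14 adjusted over the list alone, camera adjusted p = 3.8e-06, adjusted p = 0.16 with an estimated correlation). The stress cytokine GDF15 fell 4.37-fold and the ribonucleotide reductase subunit RRM2B fell 3.02-fold. In all, 19833 features changed at day 1 by edgeR, 10248 higher and 9585 lower, and 6580 of them by at least 2-fold (3843 higher and 2737 lower). The highest edgeR adjusted p among the 52 named genes that passed was 0.029.

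From day 1 to day 2, early to late mesoderm, cardiac mesoderm genes came on together, most genes of the endoderm list rose and epithelial genes fell. MSGN1, a factor of presomitic mesoderm, rose from 0.015 ± 0.013 to 11.5 ± 0.95 CPM, a log2 fold change of 9.46 ± 0.42. Of 18 cardiac mesoderm genes, 17 rose and KDR, the VEGF receptor, did not pass at 182 ± 5.1 and 153 ± 6.4 CPM (18 adjusted over the list alone, camera adjusted p = 3.4e-110). FOXC1, a forkhead factor of mesoderm, rose 278-fold to 32.5 ± 2.2 CPM, GATA6 rose from 0.844 ± 0.21 to 150 ± 5.1, and PDGFRA, whose span shares reads with RP11-231C18.3, rose 186-fold. FOXC2 rose from 2 counts to 499, a ratio of 234 (95% counting interval 64.5 to 1941), with a log2 fold change of 7.62, or 10.28 without day 1 replicate 3. Of 22 streak and early mesoderm genes, 14 rose, EVX1, NODAL, FGF8, CDX1 and CDX2 fell, and MIXL1, WNT3 and SP5 did not pass (19 adjusted over the list alone, camera adjusted p = 4.3e-37). The Notch ligand DLL3 rose from 0.909 ± 0.12 to 151 ± 4.7 CPM, FGF17 rose 151-fold and APLNR rose 131-fold to 584 ± 26. Of 21 cardiac transcription factors, 9 rose, 4 fell, among them TBX5, and 8 did not pass (13 adjusted over the list alone, camera adjusted p = 2.3e-12). HAND1 rose 92.3-fold to 5.63 ± 0.47 CPM and GATA4 24.2-fold to 37.6 ± 1.9, and HOPX rose to 1.78 ± 0.13 CPM (log2 fold change 5.84 ± 0.39, or 6.62 without day 1 replicate 3), whereas NKX2-5, at 0.026 ± 0.0055 and 0.0526 ± 0.012 CPM, did not pass.

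Of 14 genes of epithelial to mesenchymal transition, 9 rose between days 1 and 2 and the epithelial members CDH1, EPCAM, CLDN6, CLDN7 and ESRP1 fell (14 adjusted over the list alone, camera adjusted p = 7.8e-13). The repressors of epithelial genes SNAI2, ZEB2 and ZEB1 rose 43.3-fold, 26.5-fold and 13.2-fold, and TWIST1 rose 10.7-fold. Of 15 epithelial junction genes, 14 fell and CLDN3 did not pass (14 adjusted over the list alone, camera adjusted p = 8.8e-16). EPCAM fell from 114 ± 7.2 to 37.5 ± 3.2 CPM, the tight junction gene OCLN fell 2.99-fold, the protease ST14 fell 3.26-fold and CLDN7, which overlaps RP1-4G17.5, fell 3.31-fold. Of 20 pluripotency genes, 17 fell, SALL4 and FGF4 rose and LIN28B did not pass (19 adjusted over the list alone, camera adjusted p = 1.7e-13). GDF3, a TGF-beta ligand, fell 17.6-fold, NANOG fell from 71.9 ± 7.5 to 8.79 ± 0.14 CPM and the telomerase gene TERT fell 3.98-fold. Of 18 definitive endoderm genes, 11 rose, AFP and TRIM71 fell and FOXA3, TTR, APOA1, APOB and ALB did not pass (13 adjusted over the list alone, camera adjusted p = 1.4e-13). SOX17, an endoderm and endothelial factor, rose from 0.0259 ± 0.016 to 11 ± 0.092 CPM, the secreted antagonist CER1 rose 108-fold to 185 ± 24, and the chemokine receptor gene CXCR4 rose 38.2-fold. Of 21 calcium handling and ion channel genes, 9 rose, 7 fell and 5 did not pass (17 adjusted over the list alone, camera adjusted p = 0.04, adjusted p = 0.22 with an estimated correlation). The potassium channel gene KCNJ5 rose 238-fold and KCNJ2 rose 17.4-fold. That camera call was lost without day 1 replicate 2 (adjusted p = 0.089), without day 14 replicate 2 (adjusted p = 0.08) or without day 14 replicate 3 (adjusted p = 0.054). All 13 mitochondrially encoded genes fell, MT-ND2 by 2.21-fold (13 adjusted over the list alone, camera adjusted p = 0.00028, adjusted p = 0.34 with an estimated correlation).

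Among single genes, FSHR rose 221-fold to 122 ± 3.4 CPM at day 2, sharing reads with the overlapping RP11-460M2.1, and the transcript RP11-405K6.1 rose 245-fold. The lncRNA PCAT14 fell from 823 ± 81 to 57.4 ± 10 CPM, the neuropeptide precursor VGF fell 15-fold, TRIML2 14.3-fold, the matrix gene THBS2 11.8-fold and RP13-238F13.3, which overlaps NKX1-2, 11.1-fold. Between days 1 and 2, 16478 features changed by edgeR, 7992 higher and 8486 lower, 6022 of them by at least 2-fold (3369 higher and 2653 lower), and the highest adjusted p among the 51 named genes that passed was 0.014.

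From day 2 to day 4, late to cardiac mesoderm, every tested gene of the streak list fell and heart regulators and contractile genes rose. TBX5, a T-box factor required for heart formation, rose from 3 counts to 7645, a ratio of 2427 (95% counting interval 830 to 11773), with a log2 fold change of 11.07, or 11.92 without day 2 replicate 1. SMYD1, a muscle methyltransferase, rose from 0.0314 ± 0.0097 to 62.2 ± 6.8 CPM, and TBX2 and HAND2, whose spans share reads with yylncTBX2 and HAND2-AS1, rose to 36.7 ± 1.2 and 49.5 ± 2.3 CPM. Of 21 cardiac transcription factors, 17 rose, GATA6, TBX3 and HOPX fell and IRX4 did not pass (20 adjusted over the list alone, camera adjusted p = 8.6e-40). Of 25 sarcomere genes, which encode the contractile filaments and their anchors, 21 rose, TNNI3 and MYOM1 fell and MYL2 and TCAP did not pass (23 adjusted over the list alone, camera adjusted p = 9.1e-30). The atrial light chain gene MYL4 rose 522-fold to 77.4 ± 2.2 CPM, cardiac troponin T (TNNT2) rose from 0.38 ± 0.088 to 61.6 ± 1.7, the myosin heavy chain gene MYH6 rose 129-fold and slow troponin I (TNNI1) rose 53.6-fold. Of 13 atrial and ventricular markers, 8 rose, among them the atrial light chain gene MYL7 (48.5-fold), KCNA5 fell, and NPPA, MYL2, SLN and IRX4 did not pass (9 adjusted over the list alone, camera adjusted p = 8.5e-05). Of 12 BMP targets, 9 rose, MSX1 and ATOH8 fell and ID1 did not pass (11 adjusted over the list alone, camera adjusted p = 2.7e-06). SMAD6, which restrains BMP signalling, rose from 42.0 ± 3.3 to 376 ± 14 CPM, and SMAD9, ID2 and MSX2 rose 9.82-fold, 4.9-fold and 4.38-fold.

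All 22 streak genes fell between days 2 and 4 (22 adjusted over the list alone, camera adjusted p = 7.9e-69). MSGN1 fell from 3295 counts to 3, a ratio of 1153 (95% counting interval 394 to 5594; log2 fold change −9.98, or −10.81 without day 4 replicate 3), CER1 fell from 185 ± 24 to 0.3 ± 0.067 CPM, CDX2 fell 202-fold and FGF17 165-fold. Of 10 targets of NODAL and activin signalling, 9 fell and 1 rose (10 adjusted over the list alone, camera adjusted p = 1.4e-07). The organiser gene GSC fell 151-fold and the T-box gene EOMES fell 46.5-fold. Of 15 WNT feedback targets, 12 fell and LEF1, RNF43 and LGR5 rose (15 adjusted over the list alone, camera adjusted p = 3.4e-11). The WNT antagonist genes DKK4 and DKK1 fell 33.4-fold and 20.1-fold and CDX1 fell 77.2-fold. Of 20 pluripotency genes, 19 fell and DPPA2 did not pass (19 adjusted over the list alone, camera adjusted p = 6e-19). NANOG fell 35.9-fold to 0.244 ± 0.033 CPM, FGF4 fell 238-fold, TDGF1, a NODAL co-receptor, fell 28.5-fold, and ESRG, which lies inside CACNA2D3, fell 33.9-fold. Of 15 neural genes, 7 fell, LHX2 rose and 7 did not pass (8 adjusted over the list alone, camera adjusted p = 0.00044). ZIC2 fell 43.3-fold and STMN2 fell 41.0-fold.

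All 25 genes of the S and G2/M phases of the cell cycle fell between days 2 and 4 (25 adjusted over the list alone, camera adjusted p = 1.2e-09, adjusted p = 0.16 with an estimated correlation). Ribonucleotide reductase RRM2 fell 3.37-fold, the kinase BUB1 fell 3.01-fold and the replication factor MCM6 fell 2.94-fold. Of 21 glycolysis genes, 17 fell, PFKM, PFKP and SLC2A3 rose and ENO2 did not pass (20 adjusted over the list alone, camera adjusted p = 4.8e-07, adjusted p = 0.25 with an estimated correlation). PGK1 fell from 315 ± 25 to 78.6 ± 7.1 CPM and the hexokinases HK1 and HK2 fell 3.98-fold and 3.77-fold. Of 18 endoderm genes, 10 rose, SOX17, FOXA3, CER1, GATA6 and TRIM71 fell and FOXA2, CXCR4 and AFP did not pass (16 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.14 with an estimated correlation). The apolipoprotein gene APOB rose from 0.72 ± 0.032 to 33.6 ± 1.9 CPM, the liver factor HNF4A rose 18.4-fold, and TTR rose from 2 counts to 238, a ratio of 113 (95% counting interval 31 to 941). The endoderm call was lost without day 1 replicate 2 (camera adjusted p = 0.08) or without day 1 replicate 3 (adjusted p = 0.11). Of 12 epicardial genes, which mark the outer layer of the heart, 8 rose, ALDH1A2 and MSLN fell and UPK3B and SEMA3D did not pass (10 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.2 with an estimated correlation). TBX18 rose 21.8-fold and LRRN4 12.9-fold, while BNC1 (54.0-fold) and TCF21 (44.8-fold) share reads with longer overlapping transcripts.

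Among single genes, the synaptic organiser CBLN2 rose from 0.0459 ± 0.018 to 105 ± 3.7 CPM at day 4 and PLSCR5 rose from 1 count to a ratio of 2966 (95% counting interval 532 to 117197; log2 fold change 11.05, or 12.85 without day 2 replicate 1). LZTS1 fell from 261 ± 11 to 0.62 ± 0.024 CPM together with LZTS1-AS1 inside it (408-fold), and the neurotensin gene NTS fell from 338 ± 21 to 1.06 ± 0.19 CPM together with AC016993.1, which lies inside it. Between days 2 and 4, 22839 features changed by edgeR, 10804 higher and 12035 lower, 10739 of them by at least 2-fold (5461 higher and 5278 lower), and the highest adjusted p among the 67 named genes was 0.0024.

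From day 4 to day 6, cardiac mesoderm to progenitors, the contractile and calcium handling genes rose to high levels, with smooth muscle and endothelial markers beside them. MYBPC3, cardiac myosin binding protein C, rose from 0.147 ± 0.031 to 165 ± 13 CPM, a log2 fold change of 10.12 ± 0.15. Of 25 sarcomere genes, 24 rose and MYL2, the ventricular light chain gene, did not pass (24 adjusted over the list alone, camera adjusted p = 5.1e-112). The alpha and beta myosin heavy chain genes MYH6 and MYH7 rose 189-fold and 197-fold, MYH7 to 122 ± 5.9 CPM, and the M-band gene MYOM1 rose from 2.04 ± 0.15 to 266 ± 22. Of 21 calcium handling and ion channel genes, 16 rose, KCNJ2 and GJA1 fell and KCNQ1, KCNJ3 and CACNA1G did not pass (18 adjusted over the list alone, camera adjusted p = 2.5e-27). The sodium-calcium exchanger SLC8A1 rose 63.2-fold and triadin (TRDN), a partner of the calcium release channel, 63.1-fold to 419 ± 63 CPM, and SRL and KCNJ5 rose 18-fold and 16.4-fold. Of 13 atrial and ventricular markers, 10 rose, NR2F1 fell and MYL2 and KCNJ3 did not pass (11 adjusted over the list alone, camera adjusted p = 2.8e-17). Of 21 cardiac transcription factors, 14 rose, GATA6, HAND2, ISL1 and HEY1 fell and GATA5, HAND1 and PROX1 did not pass (18 adjusted over the list alone, camera adjusted p = 0.00013). The ventricular factor IRX4 rose 32.2-fold to 12.6 ± 2 CPM, NKX2-5, a core cardiac homeobox factor, rose from 3.24 ± 0.14 to 56.1 ± 2.3, and HOPX rose 6.8-fold.

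Of 12 smooth muscle genes, 10 rose at day 6, MYLK fell and SMTN did not pass (11 adjusted over the list alone, camera adjusted p = 4.4e-23). SYNPO2 and LMOD1, which bind actin, rose 23.8-fold and 13.7-fold, and the actin gene ACTA2, which shares its span with STAMBPL1, rose to 228 ± 15 CPM. Of 18 endothelial genes, 15 rose, VWF and ETV2 fell and CLDN5 did not pass (17 adjusted over the list alone, camera adjusted p = 2.4e-10). VE-cadherin (CDH5) rose from 0.558 ± 0.24 to 23.6 ± 4.4 CPM, and TIE1, PECAM1 and ERG rose 17.6-fold, 17.2-fold and 14.4-fold. Of 22 fatty acid oxidation genes, 20 rose and CPT2 and CD36 did not pass (21 adjusted over the list alone, camera adjusted p = 2.4e-15). PPARGC1A, a coactivator of mitochondrial biogenesis, rose 34.5-fold to 163 ± 19 CPM, and ACSL1, FABP3 and SLC25A20, which activate and carry fatty acids, rose 13-fold, 4.92-fold and 3.46-fold. Of 33 nuclear genes of oxidative phosphorylation, 28 rose and 5 did not pass (28 adjusted over the list alone, camera adjusted p = 1.5e-12, adjusted p = 0.2 with an estimated correlation). Cytochrome c (CYCS) rose 3.04-fold and SDHA 2.99-fold, and COX6A2, the muscle form of a cytochrome oxidase subunit, went from 0 to 383 counts, at least 148-fold higher against a floor of 3 counts.

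Of 18 endoderm genes, 9 rose at day 6, 7 fell and FOXA2 and CXCR4 did not pass (17 adjusted over the list alone). The camera test did not pass (adjusted p = 0.085) unless day 6 replicate 2 was left out (adjusted p = 0.032). AFP, alpha-fetoprotein, rose from 0.0334 ± 0.023 to 19.4 ± 8.3 CPM, a log2 fold change of 9.12 ± 0.55 that was 9.82 without day 4 replicate 3. The transport proteins TTR, APOA2 and APOA1, which overlaps APOA1-AS, rose 31.1-fold, 13.3-fold and 10.7-fold, and SERPINA1, the antitrypsin gene, rose from 3 counts to a ratio of 1116 (95% counting interval 382 to 5416), with a log2 fold change of 9.94, or 12.95 without day 4 replicate 3. Of 20 pluripotency genes, 14 fell, GDF3 rose and NANOG, DPPA2, TDGF1, LEFTY1 and FGF4 did not pass (16 adjusted over the list alone, camera adjusted p = 3.6e-10). VRTN fell 10.8-fold, POU5F1 fell from 13.6 ± 2.1 to 1.46 ± 0.25 CPM, although it shares reads with TCF19, and L1TD1 fell 6.13-fold. All 25 cell cycle genes fell (25 adjusted over the list alone, camera adjusted p = 1.3e-15, adjusted p = 0.073 with an estimated correlation). E2F1 fell 2.67-fold and the kinases AURKB and CDK1 fell 2.49-fold and 2.47-fold. Of 12 retinoic acid pathway genes, 7 fell, RARA and DHRS3 rose and 3 did not pass (9 adjusted over the list alone, camera adjusted p = 0.00026). The retinoic acid degrading enzymes CYP26A1 and CYP26C1 fell 18-fold and 10.8-fold, and the binding protein gene CRABP1 fell 6.21-fold.

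Among single genes, ASB2, a ubiquitin ligase subunit of muscle, rose from 0.0998 ± 0.025 to 67.7 ± 2.3 CPM at day 6, and AC002465.2 and RP11-506B6.6 rose with WNT2 and LAMA4, in which they lie (501-fold and 504-fold). The nitric oxide synthase gene NOS2 fell from 47.8 ± 1.1 to 0.806 ± 0.1 CPM and the bile salt pump ABCB11 fell 42.1-fold. PGA3 (30.4-fold), PGA4 (27.9-fold) and the overlapping CTD-2331C18.5 (28.1-fold) fell together, and reads of these near-identical paralogs cannot be assigned with certainty. Between days 4 and 6, 17097 features changed by edgeR, 8775 higher and 8322 lower, 6713 of them by at least 2-fold (4140 higher and 2573 lower), and the highest adjusted p among the 67 named genes that passed was 1e-04.

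From day 6 to day 8, progenitors to early cardiomyocytes, the fewest features changed among steps of consecutive days, most fatty acid oxidation genes and 11 of 21 calcium handling and ion channel genes rose, and 16 of 25 cell cycle and 11 of 18 endothelial genes fell. NPPA, the atrial natriuretic peptide gene, which overlaps NPPA-AS1, rose 6.63-fold to 30.3 ± 4.5. Of 21 calcium handling and ion channel genes, 11 rose, KCNJ3, GJA1 and CACNA1D fell and 7 did not pass (14 adjusted over the list alone, camera adjusted p = 1.7e-05). The calcium channel gene CACNA1G rose 4.12-fold and the connexin gene GJA5 2.4-fold, and KCNJ3 fell from 43.5 ± 18 to 14.1 ± 3.2 CPM, a call lost when only the 6 libraries of both days were fitted (edgeR adjusted p = 0.062). Of 25 sarcomere genes, 13 rose, MYOM2 fell and 11 did not pass (18 adjusted over the list alone, camera adjusted p = 1.3e-08, adjusted p = 0.086 with an estimated correlation). The Z-disc genes MYOZ2 and TCAP rose 2.44-fold and 2.36-fold and MYL2 went from 0 to 24 counts, at least 8.16-fold higher against the floor, whereas titin (TTN), at 16593 ± 1651 and 16381 ± 1353 CPM, did not pass. Of 13 atrial and ventricular markers, 6 rose, NR2F2 and KCNJ3 fell and MYL7, NR2F1, SLN, MYH6 and MYH7 did not pass (8 adjusted over the list alone, camera adjusted p = 0.00042). IRX4 rose 3.0-fold to 37.9 ± 7.6 CPM. Of 22 fatty acid oxidation genes, 15 rose and 7 did not pass (15 adjusted over the list alone, camera adjusted p = 5.6e-11). CPT1A rose 4.05-fold to 14.1 ± 0.51 CPM, and the electron transfer genes ETFDH and ETFB, which share reads with their neighbours, rose 1.76-fold and 1.62-fold. All 13 mitochondrially encoded genes rose, MT-ND1 from 80.3 ± 3.7 to 157 ± 13 CPM (13 adjusted over the list alone, camera adjusted p = 5.8e-10, adjusted p = 0.11 with an estimated correlation).

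Of 25 cell cycle genes, 16 fell at day 8 and 9, among them the replication genes MCM2 to MCM7 and PCNA, did not pass (16 adjusted over the list alone, camera adjusted p = 2.6e-22). TOP2A fell from 70.1 ± 1.7 to 22.6 ± 2.3 CPM and the mitotic genes MKI67, CDC20 and PLK1 fell 2.61-fold, 2.51-fold and 2.5-fold. Of 18 cardiac mesoderm genes, 7 fell, LIX1 rose and 10 did not pass (8 adjusted over the list alone, camera adjusted p = 2.7e-07). BMP4 fell 3.01-fold, APLNR 2.29-fold and ISL1, a factor of the second heart field, 2.15-fold. Of 18 endothelial genes, 11 fell, EMCN rose and 6 did not pass (12 adjusted over the list alone, camera adjusted p = 6.9e-09). Von Willebrand factor (VWF) fell from 6.41 ± 0.96 to 1.27 ± 0.23 CPM, TAL1 fell 2.97-fold and CDH5 fell 2.17-fold. Of 15 epithelial junction genes, 12 fell, CLDN6 rose and CLDN10 and ESRP2 did not pass (14 adjusted over the list alone, camera adjusted p = 3.6e-10). The splicing factor ESRP1 fell 2.69-fold. Of 18 endoderm genes, 6 fell, AFP rose and 11 did not pass (8 adjusted over the list alone, camera adjusted p = 0.00087). CXCR4 fell 7.45-fold, the endoderm factors FOXA2 and FOXA1, which overlaps TTC6, fell 4.2-fold and 3.56-fold, and AFP rose to 97.4 ± 20 CPM. Of 20 pluripotency genes, 11 fell, LEFTY1 rose and 8 did not pass (13 adjusted over the list alone, camera adjusted p = 4.3e-10). GDF3 fell 4.55-fold and ZFP42 2.46-fold.

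Among single genes, PRDM16, a transcription factor of the myocardium, rose from 8.59 ± 1.6 to 60.4 ± 6.4 CPM at day 8, C1orf95 rose 8.95-fold, the laminin gene LAMA2 5.51-fold and MLIP-AS1, which lies across MLIP, 5.09-fold. The lncRNA LINC00348 fell from 23.2 ± 9.4 to 1.40 ± 0.053 CPM, GLYATL2 12.7-fold and the overlapping pseudogene GLYATL1P2 16.4-fold, the lncRNAs DEC1 and RP11-815M8.1 10.1-fold and 8.61-fold, and SEZ6L 8.47-fold. Between days 6 and 8, 9018 features changed by edgeR, 4348 higher and 4670 lower (3805 and 5165 with upper quartile factors), 2175 of them by at least 2-fold (716 higher and 1459 lower), and the highest adjusted p among the 54 named genes that passed was 0.004. The day 6 libraries differed in matrix genes, with LUM at 74.4, 10.2 and 34.4 CPM and DCN at 7.01, 0.225 and 1.93 CPM in replicates 1, 2 and 3.

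From day 8 to day 14, early to later cardiomyocytes, ventricular myosin and natriuretic peptide genes rose, as did genes of hypoxia, glycolysis, the p53 response, stress and matrix, while mesoderm and endoderm genes fell. All of these comparisons set the 3 libraries of the other run prefix against the rest. MYL2 rose from 0.0949 ± 0.025 to 45.0 ± 12 CPM (log2 fold change 8.87 ± 0.28), and NPPB, the B-type natriuretic peptide gene, rose 52.8-fold to 113 ± 29. MYH7 rose from 141 ± 16 to 1787 ± 346 CPM, whereas MYH6 fell. Of 25 sarcomere genes, 13 rose, MYH6, MYOM2 and NEBL fell and 9 did not pass (16 adjusted over the list alone, camera adjusted p = 4.6e-10, adjusted p = 0.054 with an estimated correlation). The Z-disc genes CSRP3 and TCAP rose 6.66-fold and 6.08-fold. Of 13 atrial and ventricular markers, 6 rose, NR2F2, KCNJ3, IRX4 and MYH6 fell and NR2F1, KCNA5 and HEY2 did not pass (10 adjusted over the list alone, camera adjusted p = 0.005, adjusted p = 0.093 with an estimated correlation). NPPA rose 8.13-fold to 246 ± 65 CPM. Of 17 hypoxia genes, 16 rose and PDK1 did not pass (17 adjusted over the list alone, camera adjusted p = 5.9e-16, adjusted p = 0.066 with an estimated correlation). Day 14 replicate 2 stood apart, with the list mean 0.57 above the day mean on the log2 scale, against −0.18 and −0.39 in replicates 1 and 3. Without it the log2 fold changes of NDRG1, the regulatory enzyme gene PFKFB4 and the glucose transporter gene SLC2A1 were 2.07, 2.2 and 2.05 in place of 3.29 ± 0.5, 2.84 ± 0.31 and 2.75 ± 0.31. LOX, a collagen crosslinking enzyme, rose 26.6-fold, but its span overlaps SRFBP1 and part of its reads may belong there.

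Of 21 glycolysis genes, 18 rose between days 8 and 14 and PFKM, SLC2A3 and PDK1 did not pass (19 adjusted over the list alone, camera adjusted p = 5.9e-13, adjusted p = 0.099 with an estimated correlation), with replicate 2 again highest, 0.30 above the day mean. ENO2 rose from 3.54 ± 0.28 to 72.8 ± 37 CPM, and LDHA and PGK1 rose 4.77-fold and 4.58-fold. Of 16 p53 targets, 13 rose, TP53INP1 and FDXR fell and SESN1 did not pass (15 adjusted over the list alone, camera adjusted p = 1.3e-11). The cell cycle inhibitor CDKN1A rose from 2.76 ± 0.39 to 69.9 ± 8.9 CPM, and GDF15, PHLDA3 and ZMAT3 rose 5.42-fold, 4.92-fold and 3.54-fold. Of 18 immediate early and stress genes, 14 rose and IER2, HSPA1A, HSPA1B and DNAJB1 did not pass (14 adjusted over the list alone, camera adjusted p = 6.3e-11). IER3 rose 6.55-fold to 17.4 ± 2.6 CPM, EGR2 4.01-fold, and EGR3 and HSPA6, which share reads with longer transcripts, 4.08-fold and 17.9-fold. Of 18 fibroblast and matrix genes, 15 rose and COL6A1, DDR2 and MMP2 did not pass (16 adjusted over the list alone, camera adjusted p = 6.3e-09, adjusted p = 0.17 with an estimated correlation). The collagen gene COL1A2 rose from 161 ± 31 to 880 ± 105 CPM, and POSTN and DCN, secreted matrix proteins, rose 7.23-fold and 7.02-fold. Of 13 mitochondrially encoded genes, 9 rose and MT-ND1, MT-ND2, MT-ND5 and MT-CO3 did not pass (10 adjusted over the list alone). MT-ND4 rose 1.77-fold. Their camera test did not pass (adjusted p = 0.087) except without day 1 replicate 3 (adjusted p = 0.024) or without day 14 replicate 2 (adjusted p = 0.031).

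Of 18 cardiac mesoderm genes, 11 fell between days 8 and 14 and 7 did not pass (11 adjusted over the list alone, camera adjusted p = 2.1e-13). The WNT agonist RSPO3 fell from 129 ± 2.6 to 10.7 ± 1.4 CPM, APLNR fell 10.5-fold, LIX1, which overlaps CTD-2215E18.1, 9.76-fold and TBX3 5.72-fold. Of 21 cardiac transcription factors, 11 fell, HAND2, TBX18 and HOPX rose and 7 did not pass (14 adjusted over the list alone, camera adjusted p = 0.00022). ISL1 fell 5.43-fold, TBX2 3.63-fold and HOPX rose 10.5-fold. Of 12 BMP targets, 10 fell and MSX1 and ATOH8 did not pass (11 adjusted over the list alone, camera adjusted p = 1.7e-07). MSX2 fell 3.46-fold, ID4, which overlaps RP1-167F1.2, 2.94-fold and ID1 2.8-fold. Of 18 endoderm genes, 13 fell, SOX17, CXCR4 and KRT19 rose and GATA4 and GATA6 did not pass (16 adjusted over the list alone, camera adjusted p = 3.4e-09). APOB fell from 70.4 ± 20 to 4.19 ± 1.1 CPM, HNF4A 12.8-fold, TTR 9.71-fold and FOXA2 8.15-fold. Of 18 endothelial genes, 13 fell, FLT1, ROBO4 and EGFL7 rose and SOX18 and ETV2 did not pass (16 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.31 with an estimated correlation). TAL1 fell 4.79-fold, KDR fell 3.9-fold and EGFL7 rose 3.77-fold. Of 20 pluripotency genes, 16 fell, LEFTY1 rose and NANOG, DPPA2 and FGF4 did not pass (18 adjusted over the list alone, camera adjusted p = 9.8e-12). PRDM14 fell from 15 counts to 1, a ratio of 14.6 (95% counting interval 2.25 to 615; log2 fold change −3.47, or −5.43 without day 14 replicate 2), and the log2 fold change of GDF3 was −2.98 ± 0.42, or −3.74 without day 14 replicate 3.

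Among single genes, the circadian repressor BHLHE40 rose from 0.419 ± 0.085 to 30.5 ± 18 CPM at day 14 (log2 fold change 6.18 ± 0.4, or 5.59 without day 14 replicate 2). KLF9, a target of glucocorticoid signalling, rose 63.0-fold, the BMP antagonist GREM1 52.5-fold and the nuclear lncRNA NEAT1 from 50 ± 5.7 to 2038 ± 732 CPM. WNT2 and the overlapping AC002465.2 fell 167-fold and 210-fold, PGA3 78.8-fold, the GABA receptor gene GABRP 31.3-fold, the WNT antagonist SFRP5 26.1-fold and IFNG-AS1 22.1-fold. Between days 8 and 14, 18763 features changed by edgeR, 9280 higher and 9483 lower, 7118 of them by at least 2-fold (3774 higher and 3344 lower), and the highest adjusted p among the 67 named genes that passed was 0.018.

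Between day 0 and day 14, stem cells and cardiomyocytes, each tested member of the pluripotency, cell cycle and epithelial junction lists fell, and each of the cardiac transcription factor, sarcomere and atrial and ventricular lists rose. POU5F1 fell from 562 ± 23 to 0.266 ± 0.057 CPM, PRDM14 fell from 19783 counts to 1, a ratio of 19436 (95% counting interval 3488 to 767718; log2 fold change −13.81, or −15.77 without day 14 replicate 2), and ESRG fell from 104 ± 4.9 to 0.0194 ± 0.011 CPM. All 20 pluripotency genes fell (20 adjusted over the list alone, camera adjusted p = 3.5e-55). All 21 cardiac transcription factors rose (21 adjusted over the list alone, camera adjusted p = 4.8e-33). NKX2-5 rose from 0.0158 ± 0.0064 to 39.4 ± 3.8 CPM and SMYD1 from 0.131 ± 0.018 to 200 ± 26, and HAND2 and TBX2 from 3 and 2 counts to ratios of 4479.9 (1533 to 21726) and 1677 (464 to 13857). All 25 sarcomere genes rose (25 adjusted over the list alone, camera adjusted p = 4.3e-71). MYH6 rose from 0.0709 ± 0.017 to 1484 ± 163 CPM, MYBPC3 7442-fold and the light chain gene MYL3 to 290 ± 37 CPM (log2 fold change 13.09 ± 0.27, or 14.44 without day 0 replicate 3). MYH7 rose from 3 counts to 439375, a ratio of 149073 (51009.8 to 722874). All 13 atrial and ventricular markers rose (13 adjusted over the list alone, camera adjusted p = 1.4e-13), MYL7 to 1237 ± 223 CPM. Of 21 calcium handling genes, 20 rose and GJA1 fell (21 adjusted over the list alone, camera adjusted p = 1.7e-17). SLC8A1 rose from 30.4 ± 0.021 to 4268 ± 343 CPM, the junction protein gene JPH2 rose 102-fold and phospholamban (PLN), which lies inside CEP85L, rose 304-fold.

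All 25 cell cycle genes fell between day 0 and day 14 (25 adjusted over the list alone, camera adjusted p = 4.3e-31). RRM2 fell 47.8-fold, BIRC5 21.4-fold, AURKB 21.3-fold and MCM5 18.3-fold. All 15 epithelial junction genes fell (15 adjusted over the list alone, camera adjusted p = 2.5e-21). ESRP1 fell from 133 ± 2.2 to 1.12 ± 0.15 CPM, E-cadherin (CDH1) 97.1-fold and GRHL2 76.5-fold. Of 12 smooth muscle genes, 10 rose and KCNMB1 and MYLK fell (12 adjusted over the list alone, camera adjusted p = 4.4e-07). Desmin (DES) rose 76.3-fold and the coactivator MYOCD rose from 4.26 ± 0.59 to 298 ± 25 CPM. Of 18 fibroblast and matrix genes, 17 rose and THY1 fell (18 adjusted over the list alone, camera adjusted p = 1.7e-08, adjusted p = 0.19 with an estimated correlation). COL3A1 reached 2572 ± 285 CPM (log2 fold change 16.64 ± 0.6, or 17.54 without day 0 replicate 2) and LUM rose from 1 count to 26591, a ratio of 27066 (4857 to 1069081; log2 fold change 14.31, or 16.25 without day 0 replicate 1). Of 15 neural genes, 11 fell, PAX6, STMN2 and LHX2 rose and 1 did not pass (14 adjusted over the list alone, camera adjusted p = 2.5e-05), ZIC2 from 33.6 ± 1.7 to 0.0158 ± 0.0048 CPM. In all, 29784 features differed between day 0 and day 14 by edgeR, 15679 higher and 14105 lower, 19630 of them by at least 2-fold (10960 higher and 8670 lower), and the highest adjusted p among the 47 named genes that passed was 0.0022.

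**Figure D3:**
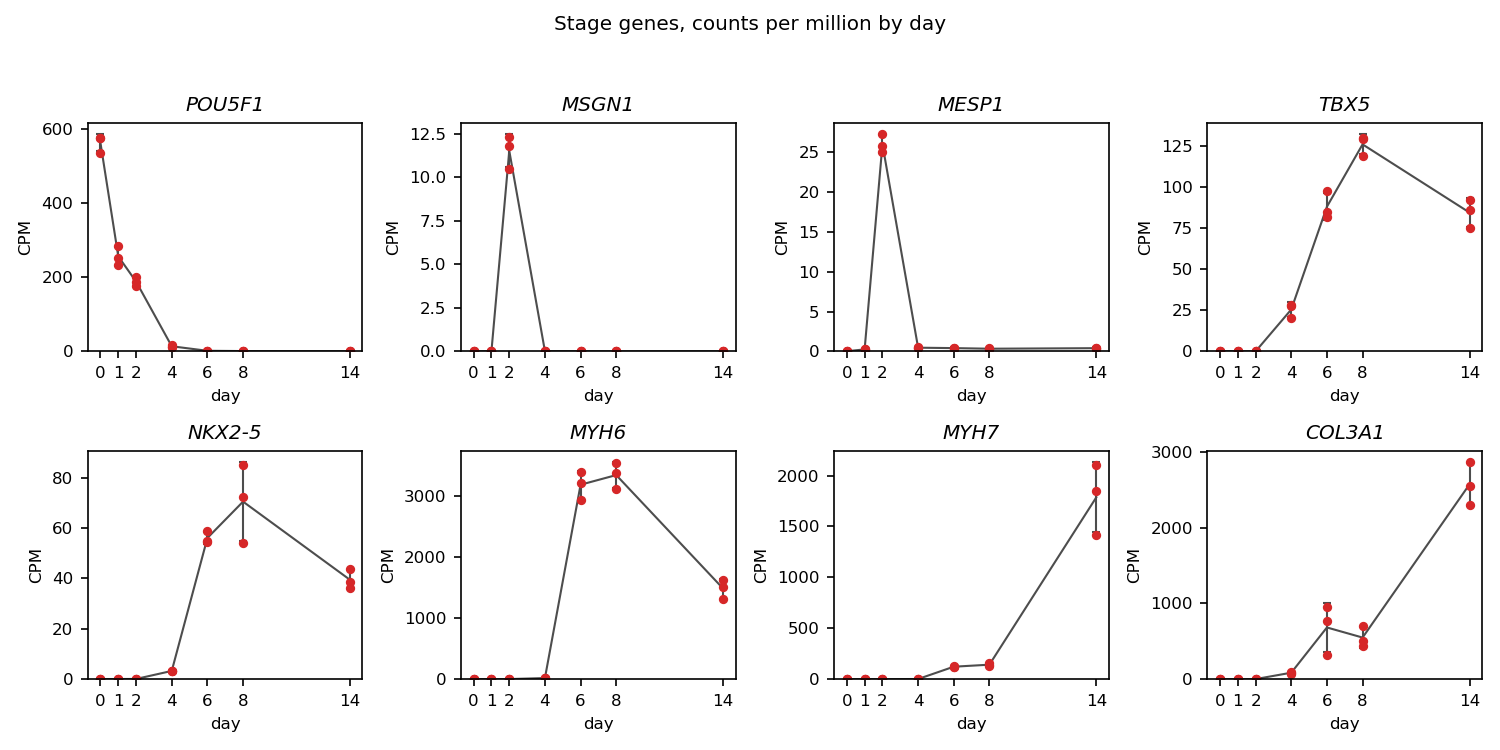
CPM on a linear axis (y) against day of differentiation (x) for POU5F1, MSGN1, MESP1, TBX5, NKX2-5, MYH6, MYH7 and COL3A1, with points for single libraries and the line through the mean of 3 libraries with SD. MSGN1 is highest at day 2 (11.5 CPM), MYH6 at day 8 (3348 CPM) and MYH7 at day 14 (1787 CPM).

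**Figure D4:**
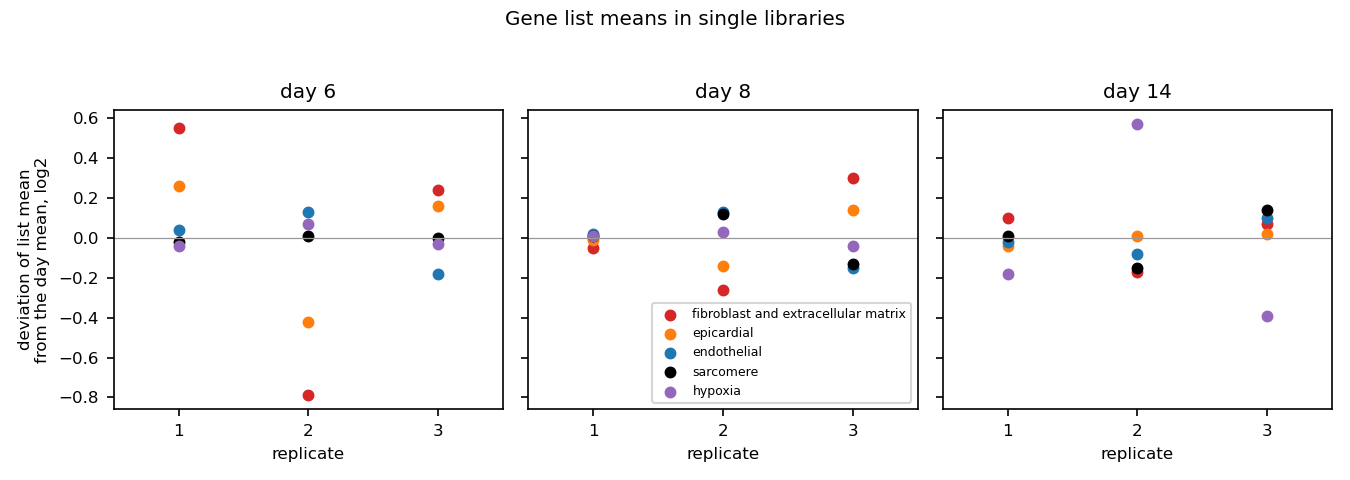
Deviation of the mean of 5 gene lists from their mean on the same day (y axis, log2) in each replicate (x axis) of days 6, 8 and 14. Fibroblast and matrix genes lie at 0.55, −0.79 and 0.24 in the day 6 libraries and hypoxia genes at 0.57 in day 14 replicate 2.

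The series title names the noncoding RNA yylncT, the mesodermal programme and the DNA methyltransferase DNMT3B. The question here is how they moved over the course. TBXT (T) lies on chromosome 6 of hg38 at 166157656 to 166168700 on the minus strand. yylncT lies on the plus strand at 166169202 to 166170199, 501 bases upstream of T, and overlaps no other feature. Counts seem to ignore strand, so minus-strand reads there would count as yylncT. yylncT rose from 0.0239 ± 0.0013 to 4.02 ± 0.25 CPM at day 1 (log2 fold change 7.32 ± 0.27, edgeR adjusted p = 2.4e-12) and to 5.81 ± 0.072 at day 2 (log2 fold change 0.53 ± 0.16, edgeR adjusted p = 0.014, or 0.064 without day 1 replicate 1). At day 4 it fell to 2 counts over the 3 libraries, a ratio of 871 (95% counting interval 241 to 7201, edgeR adjusted p = 8.2e-14), and at days 6, 8 and 14 it held at most 1 count, which gives no fold. T followed the same days, rising further from 99.1 ± 4.6 to 176 ± 12 CPM at day 2 and falling to 1.36 ± 0.24 at day 4 (log2 fold change −7.02 ± 0.13, edgeR adjusted p = 1.4e-19) and 0.213 ± 0.063 at day 6. From day 8 to day 14 T fell from 10 counts to 1, a ratio of 9.73 (1.38 to 422, edgeR adjusted p = 0.018), a call lost without day 14 replicate 1 (0.078), day 14 replicate 2 (0.07) or day 8 replicate 2 (0.078). Its log2 fold change of −2.90 was −4.87 without day 14 replicate 3. Between the first and last day yylncT went from 6 counts to 1, a ratio of 5.89 (0.715 to 271, edgeR adjusted p = 0.065), which passed without day 14 replicate 2 (0.021, log2 fold change −4.17 in place of −2.21) and under limma voom (0.0067). Of the 9 features within 100 kb of T, 4 were tested. Among them the lncRNA RP4-655C5.4 rose from 0.0281 ± 0.014 to 0.25 ± 0.022 CPM at day 1 (edgeR adjusted p = 6.4e-05) and fell at day 4 (log2 fold change −3.10 ± 0.58, or −3.77 without day 4 replicate 3, edgeR adjusted p = 0.00011). The pseudogene GAPDHP72 fell 2.15-fold at day 4 and rose 4.74-fold from day 8 to day 14, to end 1.96-fold above day 0.

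DNMT3B, a de novo DNA methyltransferase gene on chromosome 20 (32762385 to 32809356, plus strand), fell at each step, from 1065 ± 39 CPM at day 0 to 413 ± 22 at day 1 (log2 fold change −1.37 ± 0.09, edgeR adjusted p = 2.2e-10). It then fell to 227 ± 6.1 at day 2, 54.1 ± 1.7 at day 4, 33.2 ± 1.7 at day 6, 21.7 ± 0.43 at day 8 and 13.2 ± 2.6 at day 14. DNMT3A, the other de novo enzyme gene, had no single direction, at 93.4 ± 5.4, 61.4 ± 1.9, 47.6 ± 1.9, 81.6 ± 2, 61.3 ± 5.4, 86.9 ± 2.6 and 69.5 ± 1.7 CPM from day 0 to day 14. Each of these steps passed. The maintenance enzyme gene DNMT1 fell from day 1 to day 6 (106 ± 4 to 36.7 ± 4.7 CPM). Its rise at day 1 (edgeR adjusted p = 0.029) was lost without day 0 replicate 2 (0.071), day 0 replicate 3 (0.098), day 1 replicate 2 (0.1) or day 1 replicate 3 (0.062) and without the count filter (0.052). DNMT3L rose from 0.242 ± 0.08 to 0.487 ± 0.078 CPM at day 1 (edgeR adjusted p = 0.014), which was lost without day 0 replicate 2 (0.084) or day 1 replicate 3 (0.059). It fell at day 4 (log2 fold change −2.55 ± 0.36, or −3.16 without day 4 replicate 3) and rose 6.74-fold from day 8 to day 14, to 0.3 ± 0.095 CPM. The demethylating enzyme gene TET2 rose from 6.07 ± 0.3 at day 0 to 116 ± 18 CPM at day 14. The list of 9 DNA methylation genes held risers and fallers in each step described. Its camera test did not pass at day 1 (4 rose, 3 fell, adjusted p = 0.53), at day 2 (1 rose, 5 fell, adjusted p = 0.54) or between day 0 and day 14 (2 rose, 5 fell, adjusted p = 0.096, or 0.25 with an estimated correlation). Of its members, 7, 6 and 7 passed in these steps when adjusted over the list alone. At day 1 the mean of this list was 0.01 on the log2 scale and its median −0.10.

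**Figure D5:**
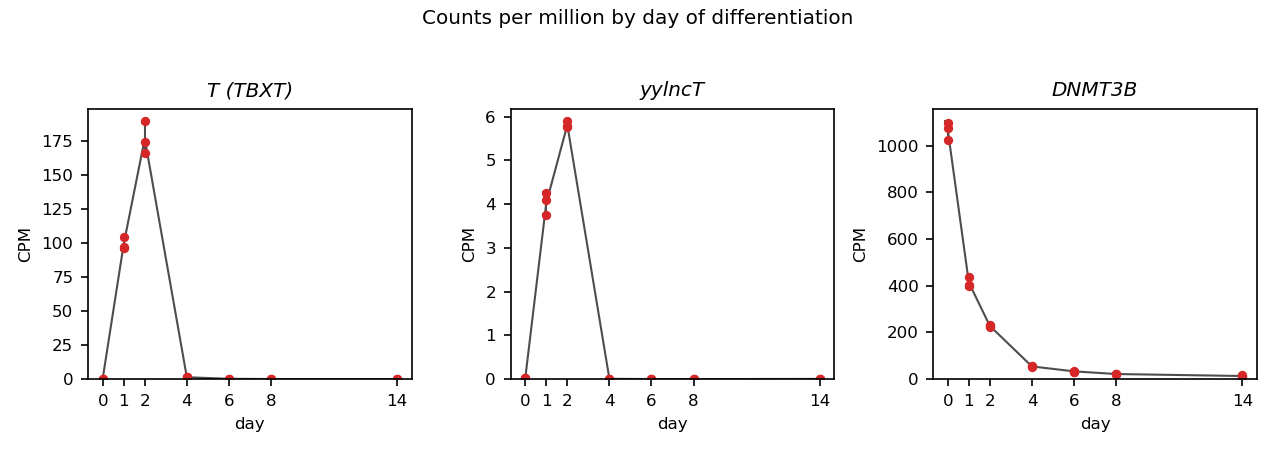
CPM (y axis, linear) of T (TBXT), yylncT and DNMT3B by day of differentiation (x axis), with points for single libraries and the line through the mean of 3 libraries. T and yylncT are highest at day 2 (176 and 5.81 CPM), when DNMT3B has fallen from 1065 to 227 CPM.

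The table pairs many noncoding features with a coding gene beside them, which raises the question of how far such neighbours moved together. For 2115 lncRNA genes with the start of a coding gene within 5 kb on the opposite strand, the median correlation of the 7 day means with that gene was 0.69, against a mean of −0.01 for permuted partners (p = 1e-04, the smallest that 10000 permutations can give, adjusted p = 1e-04). Of the pairs, 49.6% lay above 0.7 against 13.3% of permuted pairs. These correlations run over pairs, which are not independent replicates. Part of the pairs share reads. In alternatives added after the data were seen, the median was 0.49 for 966 pairs whose features do not overlap and 0.46 for 381 lncRNA genes overlapping no feature at all. Of the 2115 pairs, 955 changed in both members between days 2 and 4 and 801 of them in the same direction. For 832 yylnc features and the gene in their name, 803 of them on opposite strands, the median correlation was 0.94 (431 overlapping no feature, 0.93). The yylnc class may have been chosen by the study on these samples, so its values are not independent evidence. Of 850 tested yylnc features, 568 (66.8%) changed between days 2 and 4 (345 higher) and 711 (83.6%) from day 0 to 14 (456 higher). These shares were 68.9% and 83.7% for protein-coding genes and 59.3% and 77.1% for 442 yylnc features overlapping no other.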

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

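No alternative reversed the direction of a named gene, list or pair correlation, but which direction held more features changed in 5 steps. Higher and lower were 9712 and 9730 at day 1 by DESeq2, 9518 and 8530 at day 2 with days 0 to 8 alone, 11924 and 10912 at day 4 and 8241 and 9144 at day 6 with upper quartile factors, 8568 and 10316 at day 6 with days 0 to 8 alone, and 7038 and 6537 at day 14 with only the 6 libraries. Gene counts stayed within 1.5 times of those reported except with a threshold of at least 2-fold and where only features overlapping no other were tested, both of which test or keep fewer features by construction. With at least 2-fold the counts were 6580 at day 1, 6022 at day 2, 10739 at day 4, 6713 at day 6, 2175 at day 8, 7118 from day 8 to day 14 and 19630 from day 0 to day 14. Restricted to the 11077 tested features overlapping no other, an alternative added after the data were seen, they were 5478, 4738, 6521, 4836, 2682, 5361 and 8197, and 10454 over the course. Leaving out each library gave 17419 to 20921 at day 1, 14364 to 17672 at day 2, 21024 to 23830 at day 4, 15146 to 18166 at day 6, 6584 to 10390 at day 8, 16638 to 19072 from day 8 to day 14, 28909 to 30260 from day 0 to day 14, 36906 to 37295 over the course and 35723 to 36188 over days 0 to 8. Other scalings shifted the median fold change by at most 0.07 on the log2 scale. Days 0 to 8 fitted alone, also added later, gave 21200, 18048, 23962, 18884 and 11211 for the steps up to day 8. Without day 14, 14% of features were highest on day 6 and 19.7% on day 8, in place of 9.1% and 10.4%, as later days no longer took part.

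Of 259 set tests, 151 passed, and 62 did with an estimated correlation, all among the 151 and in the same direction. The estimate allows for members that move together, which widens the test. By step, called and held with the estimate were 19 and 6 at day 1, 20 and 7 at day 2, 19 and 9 at day 4, 20 and 9 at day 6, 21 and 12 at day 8, 27 and 8 from day 8 to day 14 and 25 and 11 from day 0 to day 14. Other scalings (upper quartile factors were added later) gave 152, the list tests without mitochondrial genes, added later, 145, and leaving out each library, also added later, 143 (without day 14 replicate 3) to 154 (without day 4 replicate 2). The replicate number as a block gave 152 list calls and 19518, 16149, 22582, 16740, 8543, 18422 and 29650 changed features, and then 3 lists gained a call, skeletal muscle at day 6 (camera adjusted p = 0.036), definitive endoderm at day 1 (0.049) and fibroblast and matrix at day 4 (0.029), and 2 lost theirs, oxidative phosphorylation at day 14 (0.052) and smooth muscle at day 4 (0.053). The labels leave open whether numbers pair the libraries. Pairs of the same number (63) had a median residual correlation of −0.003 (−0.065 to 0.082), different numbers 0. Of 21 libraries, 10 correlated best with their own number. Among the lists whose call changed with some alternative, the camera adjusted p ran over all of them from 0.036 to 0.38 (skeletal muscle, day 6), 0.02 to 0.62 (HOX genes of the A and B clusters, day 4), 0.00011 to 0.66 (cytosolic ribosomal proteins, day 14), 0.032 to 0.24 (definitive endoderm, day 6) and 0.024 to 0.66 (mitochondrially encoded, day 14). Over all alternatives, test programs and libraries left out included, the adjusted p ran from 0.0034 to 0.1 for DNMT1 and 0.0043 to 0.084 for DNMT3L at day 1, 2.6e-05 to 0.058 for FOXF1 at day 1, 4.1e-12 to 0.062 for KCNJ3 at day 8, 0.0094 to 0.078 for T from day 8 to day 14, and for yylncT 7.4e-06 to 0.064 at day 2 and 0.0067 to 0.21 from day 0 to day 14. Depth limits features with few counts, and 50.7% of simulated 1.5-fold changes were found in the simulation, which changed only 200 features.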

Other observations

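The tests of these lists were planned with those of the report, and genes named as exceptions were chosen after their values were seen. HOX genes, which pattern the body axis, came on early. Of 12 HOX genes of the A and B clusters, 9 rose at day 1 and HOXB5, HOXB6 and HOXB8 did not pass (9 adjusted over the list alone, camera adjusted p = 0.00041, adjusted p = 0.18 with an estimated correlation). HOXB7 and HOXA2 went from 0 counts to levels at least 25.3-fold and 18.4-fold over the floor, although HOX spans share many reads. At day 4, 8 rose, 3 fell and HOXB9 did not pass (11 adjusted over the list alone, camera adjusted p = 0.19, or 0.02 without day 6 replicate 2). HOXB6 had a log2 fold change of 5.27 ± 0.57 (6.21 without day 2 replicate 2). Of 17 hypoxia genes, 11 rose at day 1, CA9 and ADM fell and 4 did not pass (13 adjusted over the list alone, camera adjusted p = 0.02, adjusted p = 0.6 with an estimated correlation), and PDK1 rose 5.02-fold. Of 13 histone genes, 12 fell at day 1 and HIST1H4H did not pass (12 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.46 with an estimated correlation). All 13 fell at day 6 (13 adjusted over the list alone, camera adjusted p = 0.0004, adjusted p = 0.39 with an estimated correlation) and between day 0 and day 14 (13 adjusted over the list alone, camera adjusted p = 4.2e-09, adjusted p = 0.18 with an estimated correlation), HIST1H1B from 407 ± 13 to 15.8 ± 4.7 CPM. Of 12 retinoic acid genes, 6 rose at day 2, DHRS3 fell and 5 did not pass (7 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.11 with an estimated correlation), a call lost without day 0 replicate 1 (0.052), day 0 replicate 3 (0.054), day 1 replicate 3 (0.063), day 6 replicate 2 (0.054), day 8 replicate 3 (0.055), day 14 replicate 2 (0.06) or day 14 replicate 3 (0.058) and without mitochondrial genes (0.05). CYP26A1 rose from 2.17 ± 0.4 to 62.9 ± 6 CPM. At day 4, 3 rose, 7 fell and DHRS3 and STRA6 did not pass (11 adjusted over the list alone, camera adjusted p = 0.14), and the receptor gene RARB, which overlaps TOP2B, rose 51.8-fold. Of 19 cholesterol synthesis genes, 16 fell at day 2 and 3 did not pass (17 adjusted over the list alone, camera adjusted p = 0.00016, adjusted p = 0.3 with an estimated correlation). At day 4, 17 fell, SC5D rose and INSIG1 did not pass (19 adjusted over the list alone, camera adjusted p = 1.9e-06, adjusted p = 0.2 with an estimated correlation).

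Of 11 skeletal muscle genes, 7 rose at day 2 and CKM, MYH3, TNNT3 and TNNC2 did not pass (7 adjusted over the list alone, camera adjusted p = 0.0049, adjusted p = 0.094 with an estimated correlation), and the myogenic factor MYF5 rose 21.6-fold. At day 6 this list had 4 risers, among them the kinase gene CKM (86.3-fold), and 4 that fell, MYF5, PAX3, PAX7 and TNNT1 (8 adjusted over the list alone, camera adjusted p = 0.15). At day 14 it passed (4 rose, 3 fell, 7 adjusted over the list alone, camera adjusted p = 0.045, adjusted p = 0.22 with an estimated correlation), which was lost without day 6 replicate 2 (0.066), day 6 replicate 3 (0.052), day 8 replicate 1 (0.067) or day 8 replicate 3 (0.1), and ACTA1 rose 15-fold. Of 21 glycolysis genes, 15 rose at day 6 and 6 did not pass (17 adjusted over the list alone, camera adjusted p = 0.00017, adjusted p = 0.38 with an estimated correlation), and HK1 rose 3.14-fold. Epicardial (5 rose, 3 fell, 9 adjusted over the list alone), neural crest (4 rose, 3 fell, 8 adjusted over the list alone) and blood genes (5 rose, 5 fell, 10 adjusted over the list alone) did not pass at day 6 (camera adjusted p = 0.64, 0.51 and 0.97), although WT1, an epicardial factor, rose 16.8-fold and CD34 4.94-fold. The blood list tested as lower while its median was 0.27 and its mean 0.18. Of 33 nuclear genes of oxidative phosphorylation, 21 rose at day 8 and 12 did not pass (27 adjusted over the list alone, camera adjusted p = 5.7e-11, adjusted p = 0.24 with an estimated correlation), with UQCRQ up 1.68-fold. Of 18 lncRNAs of stem cells and heart, 5 rose and 9 fell at day 4 (15 adjusted over the list alone, camera adjusted p = 0.13), H19 from 0.203 ± 0.02 to 158 ± 10 CPM. At day 8, HAND2-AS1, BANCR and LINC00881 rose and TUNAR, LINC00261, NEAT1, XACT and EVX1-AS fell (11 adjusted over the list alone, camera adjusted p = 0.0051). At day 14, 9 rose and 7 fell (16 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.16 with an estimated correlation), with a median of 0.56 but a mean of −0.17. This call was lost without any 1 of the day 6 (0.052, 0.068 and 0.068) or day 8 libraries (0.082, 0.063 and 0.08). Between day 0 and day 14, 8 rose and 10 fell (18 adjusted over the list alone, camera adjusted p = 0.45), and HAND2-AS1 had a log2 fold change of 12.13 ± 0.18 (13.08 without day 0 replicate 3). Of 27 ribosomal protein genes, 18 rose at day 14 and 9 did not pass (20 adjusted over the list alone, camera adjusted p = 0.005, adjusted p = 0.66 with an estimated correlation), a call lost without day 14 replicate 3 (0.071), and RPS19 rose 1.58-fold. Of 20 chromatin repressor genes, 6 rose, 11 fell and EED, SETDB1 and KDM6A did not pass between day 0 and day 14 (17 adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.31 with an estimated correlation), which was lost without day 14 replicate 1 (0.064) or replicate 3 (0.061). PHC1 fell 10.3-fold, although it overlaps M6PR, and the demethylase gene KDM6B rose 13.8-fold.

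Explanations are weighed below for 3 patterns. In each, the tests said to be chosen later were chosen only after the result was seen. Hypoxia, glycolysis, p53 and stress genes rose together at day 14, with a mean log2 fold change of 1.44 ± 0.13 (SE) over 70 members. The SE and the intervals treat members as independent, although they move together, and with an estimated correlation the hypoxia and glycolysis calls did not hold (adjusted p = 0.066 and 0.099). Day 14 replicate 2 lay 0.57 and 0.30 above the day mean in these lists. Bias from GC content and length could raise such genes together, but relative to a curve on both the mean was 1.37 (95% interval 1.1 to 1.63), a test fixed before. A larger share of mitochondrial transcripts could shift all other features, but it would shift them alike, and the members exceeded the mean of the other features not encoded in mitochondria by 1.43 (1.16 to 1.69), a test chosen later. Another sequencing run may also have contributed, and as 0 day 14 libraries carry the prefix of the other days, this stays open and run and day cannot be told apart.

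Noncoding features and the coding gene beside them moved together. Reads counted in both features could produce this, but for lncRNA genes overlapping no feature the median correlation was 0.46, against an upper permutation limit of 0.05, a test chosen later. Reads running past annotated ends could reach the noncoding feature. Among 58 pairs with starts more than 2 kb apart the median was 0.51 (permutation p = 1e-04, upper permutation limit 0.19), a test fixed before. The distance was taken between starts, so the ends of pairs facing each other may still lie close, and the test cannot decide this. Neighbours might move together whatever their orientation, which stays open. The median correlation was 0.40 with the partner and 0.12 with the next nearest coding gene (median difference 0.11, permutation p = 4e-04, 314 pairs, 197 higher), a test chosen later, and 0.93 and 0.63 for 291 yylnc features. The partner lay nearer (median gap 259 against 19884 bases for lncRNA genes). With the other gene as near the median difference was −0.04 (16 of 314 pairs) and 0.02 (9 yylnc pairs), so orientation and distance cannot be told apart.

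Fibroblast and matrix genes deviated together between the day 6 libraries, a pattern picked from 10 lists tested for joint deviation on days 6, 8 and 14. The endoderm list had been planned first and had a mean correlation of −0.01, equal to random lists (−0.01), and the matrix list was taken up afterwards as the highest at 0.63 (permutation adjusted p = 5e-04 against random lists), followed by sarcomere at 0.39, smooth muscle at 0.25, endothelial at 0.24 and epicardial at 0.15. Scaling had removed shifts of all lists by depth or RNA composition, so the sarcomere range of 0.03, a test chosen later, cannot address them. The matrix list still ranged over 1.34. Relative to a curve on GC content and length the difference was 1.33 (0.75 to 1.91), a test fixed before. A share of non-myocyte cells that differed between cultures may explain it, and of 4 lists tried later the epicardial one followed the matrix list over 9 libraries (r = 0.97, exact permutation p = 0.019 and adjusted p = 0.076 over the 4 lists by 216 permutations within days, rho = 0.87, exact permutation p = 0.056, r = 0.85 without the 2 farthest libraries), which leaves this open. For the endothelial, smooth muscle and sarcomere lists r was −0.52, 0.1 and −0.17 (exact permutation p = 0.33, 0.58 and 0.5).

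Regrouping mixes distinct days in a group and widens its spread, so fewer changed features were bound to follow, which decides nothing. Each step has 10 splits of its 6 libraries, too few for a share under 0.05, and only the real split reached the real count. The highest other count was 116 at day 8 and 0 to 5 in the other steps. Over the course the highest other of 100 groupings gave 11221 features, and 7966 without day 14.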
